A study of Homo sapiens with 2 samples.

How the data were processed

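The data came from HITS-CLIP, in which RNA crosslinked to a protein by ultraviolet light is recovered with an antibody against that protein and sequenced as short tags. The 2 libraries were biological duplicates from MDA-231-LM2 cells, a lung-metastatic derivative of the human breast cancer line MDA-MB-231. The title, the design text and the antibody label name SF3B1 as the target, whereas the extract protocol in the labels names SNRBP2. SF3B1 was taken as the target here, and the difference was left open. There was 1 group and no control or input sample, so no comparison between conditions was made.

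The authors deposited 1 list of peaks called on the pooled tags of both libraries, which gives no value for a single library. No replicate error, interval between replicates or depth per library was therefore known. Per the file's name, the authors kept unique tags, significant peaks and an interval bounded at a set part of the peak's height. Per the submitters' processing notes, cutadapt 2.3, BWA 0.7.17 and the hg38 build were used; the peak caller, its threshold and the gene annotation were not given in the sources used here. The deposited signal of each peak is its height, the number of pooled tags at its top, with no normalization; it is the authors' own value and served only to describe, rank or filter peaks within the list. The deposited text field of each peak also holds a gene number, the height expected for that gene and a p-value, and the highest p-value listed was 0.0499. The height column equalled the height in this field in all 1587 rows.

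Gene numbers were named through the RefSeq gene table of GRCh38.p14, where 1190 of 1191 numbers matched. Rows with the same chromosome, start, end and strand were counted once. A listed gene was assigned to an interval only if its RefSeq span held the interval's midpoint; an interval inside more than 1 listed gene was counted for each. The table holds gene spans without strand or exons, and no genome sequence was used. Exon, intron and splice site classes, windows at 3′ and 5′ splice sites, exon starts against ends, base composition, pentamers, folding energy and splice site features had been planned and were not analysed here. Intervals were instead put into 6 classes by midpoint, in this order: rRNA gene, small noncoding RNA gene of at most 500 nt, pseudogene of a small noncoding RNA by its symbol, protein-coding gene, long noncoding RNA or pseudogene, and no listed gene. These classes, and the regions tested below, were chosen after the list had been seen. The class of small RNA pseudogenes was added last, after the heights of 5 classes had been tested, and the result of those 5 classes is given among the alternatives.

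The number of intervals in a region was tested against uniform placement over the span of the host gene with an exact two-sided Poisson-binomial test, with Benjamini-Hochberg adjustment over 5 regions. The first and last 1 kb were tested in protein-coding genes of at least 3000 nt, with the gene's direction taken from the strand of the interval. Of 21 gene lists fixed before the data were examined, 18 were tested by a two-sided Fisher's exact test of members with an interval against all other protein-coding genes, with adjustment over the 18, and 3 of noncoding or intronless genes were given as counts only. Of their 679 entries, 677 matched the RefSeq table. Shares have exact Clopper-Pearson 95% intervals, which treat genes as independent and cover counting error only. Heights of each class were set against all other intervals by a two-sided permutation test of the difference in median log2 height with 100000 resamples. The tests compare intervals or genes within 1 pooled list, so their p-values say nothing of the spread between cultures.

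Named genes followed a rule fixed before the data were examined: the 10 genes with the highest interval, the 10 with the most intervals, the 3 highest intervals of each class, up to 3 members of each list with the highest intervals, and SF3B1. The part of the rule on 3′ splice sites was not run, and other names were chosen after their values were seen. Some items are not reported here. Alternatives were the intervals above the median height, removal of intervals at rRNA or small RNA genes or on the mitochondrial chromosome, merging within 50 nt, 1 interval per gene, any overlap of 1 nt, the mean in place of the median, other gene backgrounds and the gene numbers as listed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

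The tests were also run on 20 sets of simulated data each. For gene lists over 19987 genes, 99.4% of lists with 40% of members planted were called, and 0.556% of lists without an effect. All genes outside the planted lists were equally likely to hold an interval. These rates therefore do not cover effects of gene span or transcript level. The planted 40% lies above the share of every list that was not called, so power for such lower shares was not tested. For regions over 1355 intervals, 60 intervals planted in the last 1 kb were called in 100% of simulations, and 1% of tests were called under uniform placement. The 60 came on top of intervals placed uniformly. That rate does not cover the smaller excess observed there, 64 against 49.3 expected. The host genes were kept as listed, so hosts that entered the list only through a nested interval were not simulated. For heights over 1406 intervals, a 2-fold rise of the small RNA class was called in 100% of simulations, and 0% of class tests with heights in random order.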

Results

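SF3B1, the largest subunit of the SF3b complex of the U2 small nuclear ribonucleoprotein (snRNP), contacts pre-mRNA around the branch point. Its RNA contacts were mapped by HITS-CLIP in MDA-231-LM2 breast cancer cells, with 2 biological replicates in 1 group, to locate binding sites across the transcriptome. The deposited list pooled both replicates, so values below have no replicate error, and the tags of each library were not known.

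Most intervals lay in protein-coding genes, at low heights, while the tallest lay in a few noncoding RNAs. The list held 1406 distinct intervals in 1587 rows, 736 on the plus and 670 on the minus strand. Their median height was 7 tags, with quartiles of 6 and 11 and a range of 3 to 248. The median width was 43 nt, and 808 intervals (57.5%) were 42 to 44 nt wide. The 28 intervals of 50 tags or more held 19.1% of the summed heights. An interval lay in 1057 of 19987 protein-coding genes (5.29%), of which 871 held 1 interval, 137 held 2 and 49 held 3 or more. SF3B1 itself held 1 interval, at chromosome 2, 197418584 to 197418626 on the minus strand (hg38, as for all positions), with a height of 9 tags.

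Which transcripts carried tags was first described by class. With no control or input sample and no transcript level, contact with SF3B1 was not told apart from background of abundant RNAs. The tallest interval, 248 tags at chromosome 11, 62841670 to 62841715 (minus strand), was listed under WDR74 but lay inside RNU2-2, a gene of the U2 snRNA, the RNA partner of SF3B1. MALAT1, a nuclear long noncoding RNA, followed with 206 tags at chromosome 11, 65505229 to 65505273, and 2 further intervals of 128 and 106 tags. RMRP, the RNA of the RNase MRP, reached 203 tags, and RN7SK, the 7SK RNA that restrains transcription elongation, 142 tags. The vault RNA gene VTRNA1-2 reached 92 tags. The mitochondrial 16S rRNA, RNR2, held intervals of 195, 173 and 130 tags, and the mitochondrial 12S rRNA, RNR1, of 113, 90 and 78. The tallest intervals of VTRNA1-2, RMRP, RNR2, RNR1 and RN7SK were 2.03, 2.50, 3.12, 3.41 and 5.93 times the height expected for the gene. That of MALAT1 was 21.3 times. The interval in RNU2-2 was 172 times, but against the height expected for WDR74.

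Protein-coding genes held 1241 of the 1406 intervals, 88.3% (95% interval 86.5 to 89.9), with a median height of 7 tags. Their tallest intervals were in COL7A1, the gene of type VII collagen, with 136 tags at chromosome 3, 48582120 to 48582170 (minus strand), in NDOR1 with 99 tags at chromosome 9, 137213069 to 137213113 (plus strand), and in SNX5, a sorting nexin, with 97 tags at chromosome 20, 17947385 to 17947431 (minus strand). Small noncoding RNA genes held 53 intervals, 3.77% (2.84 to 4.90), but 9.91% of the summed heights. Pseudogenes of small noncoding RNAs held 38 intervals, long noncoding RNAs or other pseudogenes 37 and rRNA genes 8. Of the 38 intervals inside none of their listed genes, 9 lay in an rRNA gene, a small RNA gene or its pseudogene and are counted there, and 29 form the class with no listed gene. The tallest of these 29 were of 11, 10 and 10 tags, all on chromosome 21.

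Intervals in rRNA and small noncoding RNA genes were taller than the others, but the filter of the list may set part of this. The list holds significant peaks only, and the expected height was 62.41 for RNR2 and 33.14 for RNR1, against 0.91 for COL7A1. If significance was judged against that height, which the sources do not state, low peaks in RNR1 or RNR2 could not be listed. The tests of height cannot separate this from a difference between classes. The 8 rRNA intervals had a median of 101.5 tags and differed from all others by 3.85 in median log2 height (permutation test, p = 1e-05, the smallest the resamples can give; adjusted p = 6e-05). Of these 8, 6 lay in the mitochondrial genes RNR1 and RNR2, whereas the nuclear RNA5S9 and RNA28SN2 held 14 and 6 tags. With 1 interval per gene the difference was 2.51 (permutation test, adjusted p = 0.00084). Relative to the height the deposited list expects for the gene, the order differed: the median ratio was 2.74 for rRNA and 46.2 for small RNA intervals, against 167 for protein-coding ones and 650 for small RNA pseudogenes. These medians were not tested. For nested small RNAs and pseudogenes the expected height is that of the listed host gene, such as 0.01 for PHACTR1 at RNU1-11P. Intervals inside no listed gene or with no expected height above 0 were left out. That kept 24 of 38 pseudogene intervals and 1204 of 1241 protein-coding ones, so the ratios of the classes are not on an equal footing. The 53 small RNA intervals had a median of 12 tags and differed by 0.78 (permutation test, adjusted p = 6e-05). Protein-coding intervals were lower by a log2 difference of -0.36 (permutation test, adjusted p = 0.00052). That call was lost with pseudogenes of small RNAs counted with their host genes, as first run (-0.19, permutation test, adjusted p = 0.2175), and without rRNA and small RNA intervals (0, adjusted p = 1); with mean log2 heights the difference was -0.54. Small RNA pseudogenes (0.36, permutation test, adjusted p = 0.0642), long noncoding RNAs (0, adjusted p = 1) and positions with no listed gene (-0.22, adjusted p = 0.2592) did not pass the test. With mean log2 heights the latter 2 classes passed it (0.38, permutation test, adjusted p = 0.0121, and -0.58, adjusted p = 0.00176).

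**Figure D1:**
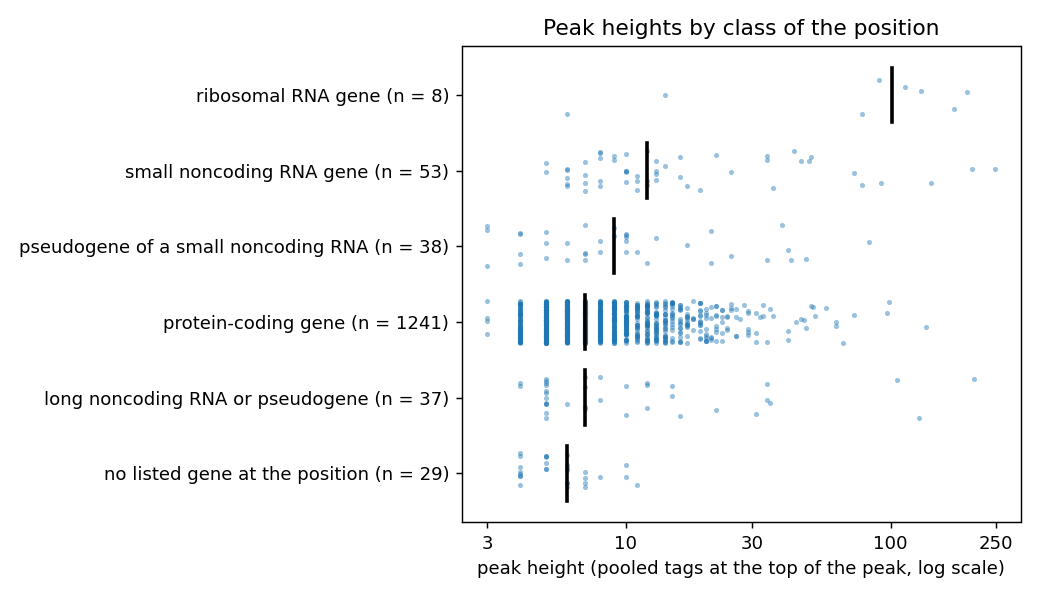
Peak height in pooled tags (log scale) of the 1406 distinct intervals by class of the position; each point is an interval, jittered vertically, and the bar is the class median. The rRNA class has a median of 101.5 tags and the small RNA class of 12, against 7 for protein-coding genes.

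Among spliceosomal RNAs, intervals fell on the U2 gene RNU2-2, on 3 RNAs of the minor spliceosome and on a single U1 gene. RNU12, which pairs with the branch point of minor introns, reached 78 tags, RNU11 73 and RNU6ATAC 49. Their expected heights were 8.73, 26.41 and 17.05. RNU4ATAC and the annotated U4, U5 and U6 genes held 0 intervals. Only unique tags were kept, so tags shared between copies would be lost. U6 has 5 annotated genes and 1277 pseudogenes. U11, U12 and U6atac have 1 gene each, and their pseudogenes were not counted. Low counts for U1, U2, U4, U5 and U6 therefore do not show absence of tags. The U1 gene RNVU1-27 held 1 interval of 5 tags, which the deposited list does not give under that gene. LOC124904146, an snRNA gene with no family in its symbol, held 1 interval of 10 tags. The deposited list gives the latter under RNU2-1, a U2 gene, and CCDC200, outside both. Of the 24 matched genes of the fixed U snRNA list, 4 held an interval: RNU11, RNU12, RNU6ATAC and RN7SK, the last not a spliceosomal RNA. RNU2-2 is not among them because the list held an older symbol. Pseudogenes also held tall intervals: RNU1-11P inside PHACTR1 (83 and 39 tags), RNA5SP298, a 5S rRNA copy inside DIP2C (48), and the U2 copies RNU2-13P inside GREB1 (42) and RNU2-6P inside RUBCNL (41). Such copies share sequence with the active genes, so the assignment of their tags is uncertain.

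Within host genes, small RNA genes held more intervals than uniform placement gave. Nested small noncoding RNA genes held 42 of 1355 intervals against 4.09 expected, a ratio of 10.3 (exact Poisson-binomial test, adjusted p = 5.57e-33). Most of the 42 lay in hosts with no interval elsewhere. Such hosts entered the test through the nested interval itself, which inflates this ratio and its p-value. In hosts that also held an interval elsewhere, a selection made after the counts were seen, the number was 13 against 2.86, a ratio of 4.54 (exact test, p = 5.95e-06). Pseudogenes of small noncoding RNAs held 35 intervals within host genes, but most of these hosts had no interval elsewhere; in hosts that did, 1 was observed against 0.22 expected, also a ratio of 4.54 (exact test, p = 0.396). Other pseudogenes held 10 against 5.76 (1.74, exact adjusted p = 0.0748). Of the 53 small RNA intervals, 36 lay in C/D box snoRNAs, most of which guide 2′-O-methylation of RNA. By gene, 36 of 357 SNORD genes (10.1%) held an interval against 1 of 182 SNORA genes (0.549%), the H/ACA box family (Fisher's exact test, two-sided, unadjusted p = 5.56e-06), a comparison chosen after the counts were seen. The tallest were SNORD96A in RACK1 (50 tags), SNORD3A (46) and SNORD35A in RPL13A (43).

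The gene ends differed from uniform placement by small amounts. The last 1 kb held 64 of 1292 intervals against 49.3 expected (1.30, adjusted p = 0.0472) and the first 1 kb 34 against 49.3 (0.69, adjusted p = 0.0323), by the exact Poisson-binomial test. The first call was lost among intervals above the median height, where the ratio was 1.14 (exact adjusted p = 0.424), with any overlap (1.27, adjusted p = 0.0563) and without genes that share an interval (1.29, adjusted p = 0.0558); the second was lost with 1 interval per gene (0.73, adjusted p = 0.0823).

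Genes of splicing regulators carried intervals far more often than other genes. SR proteins, which act on exonic enhancers, and their kinases had an interval in 14 of 23 genes (60.9%, 95% interval 38.5 to 80.3), 11.7 times the expected number (Fisher's exact test, adjusted p = 3.86e-12). The tallest were in SRSF6 (46 tags), SRSF2 (22) and SRRM2 (17). The hnRNP list, RNA-binding proteins that include splicing repressors, had 18 of 34 genes (52.9%, 35.1 to 70.2; ratio 10.2, exact adjusted p = 8.06e-14), led by HNRNPH1 (62), HNRNPA2B1 (27) and HNRNPM (20). U2 snRNP and branch site factors had 8 of 24 genes (33.3%, 15.6 to 55.3; ratio 6.34, exact adjusted p = 5.55e-05), with SNRPA1 at 10 tags and DDX46 and SF3B1 at 9. Among other spliceosome proteins, DHX38 alone of 36 genes had an interval, of 7 tags (ratio 0.525, exact adjusted p = 1). Each of the 3 lists exceeded the other spliceosome proteins in a direct Fisher's exact test chosen after the counts were seen (adjusted p = 2.83e-06 for SR proteins, 2.83e-06 for hnRNP and 0.00251 for U2 factors). Factors of the exon junction complex and nonsense-mediated decay had 4 of 16 genes (led by ACIN1 with 9 tags, SMG5 with 8 and RBM8A with 6; ratio 4.74, exact adjusted p = 0.0153), a call lost among intervals above the median height (5.17, adjusted p = 0.113).

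Genes of the cytoskeleton, translation, glycolysis, the extracellular matrix and chaperones were also above the background. Cytoskeleton and adhesion genes had 21 of 38 (55.3%; ratio 10.6, exact adjusted p = 2.8e-16), led by MACF1 (36 tags), ACTG1 (22) and VIM (18). Ribosomal protein genes had 24 of 79 (30.4%; ratio 5.85, exact adjusted p = 5.55e-12), led by RACK1 (50), RPL13A (43) and RPL10A (31), and the tallest interval of the first 2 lay at a snoRNA gene. Translation factors had 9 of 27 (ratio 6.35, exact adjusted p = 2.22e-05), with EIF4A2 at 34 tags, at SNORD2, and EEF1A1 at 14. Glycolysis had 7 of 18 (ratio 7.40, exact adjusted p = 5.55e-05), with PKM at 19, ENO1 at 16 and PFKP at 7, a call lost among intervals above the median height (4.59, adjusted p = 0.125). Extracellular matrix genes had 7 of 24 (ratio 5.55, exact adjusted p = 0.000399), with LAMC1 at 21, CCN1 at 17 and THBS1 at 11. Chaperones had 7 of 28 (ratio 4.75, exact adjusted p = 0.00101), with HSP90B1 at 24, HSPA8 at 14, at SNORD14E, and CCT6A at 10. Among intervals above the median height, the ratios were 20.1 for SR proteins, 18.7 for hnRNP, 20.2 for the cytoskeleton, 11.4 for ribosomal proteins and 10.8 for translation factors. Against genes of like span, the ribosomal protein ratio was 16.3. The proteasome, oxidative phosphorylation and mitochondrial ribosome lists had been set as an expressed background, with an interval in 7 of 144 genes (4.86%). Against it, the ratios were 12.5 for SR proteins, 10.9 for hnRNP and 6.25 for ribosomal proteins. The transcript levels of these lists were not known, so this background does not separate abundance from binding.

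The other lists did not differ from the background in Fisher's exact test. Genes with junctions known to change in SF3B1-mutant cells or under SF3B1 modulators had 3 of 16 (BRD9, ANKHD1 and SERBP1; ratio 3.55, exact adjusted p = 0.0807). The proteasome had 3 of 31, oxidative phosphorylation 3 of 59 with NDUFV1 at 26 tags, proliferation genes 2 of 29 (CCND1 and MCM4) and the mitochondrial ribosome 1 of 54 (MRPS25). The lung metastasis signature of this line had 0 of 16 genes and markers of other cell types 0 of 23, with upper limits of 20.6% and 14.8%. As counts only, 8 of 22 nuclear and snoRNA host long noncoding RNAs and 1 of 56 histone genes (H2BC5) held an interval. Among the 8, the tallest interval of SNHG29, SNHG6, ZFAS1 and SNHG5 lay at a snoRNA gene. So did 1 of 2 intervals of 22 tags in SNHG1. The intervals of MALAT1, NEAT1 and SNHG16 lay outside small RNA genes. No transcript level was used, so abundance was not separated from binding in any list.

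**Figure D2:**
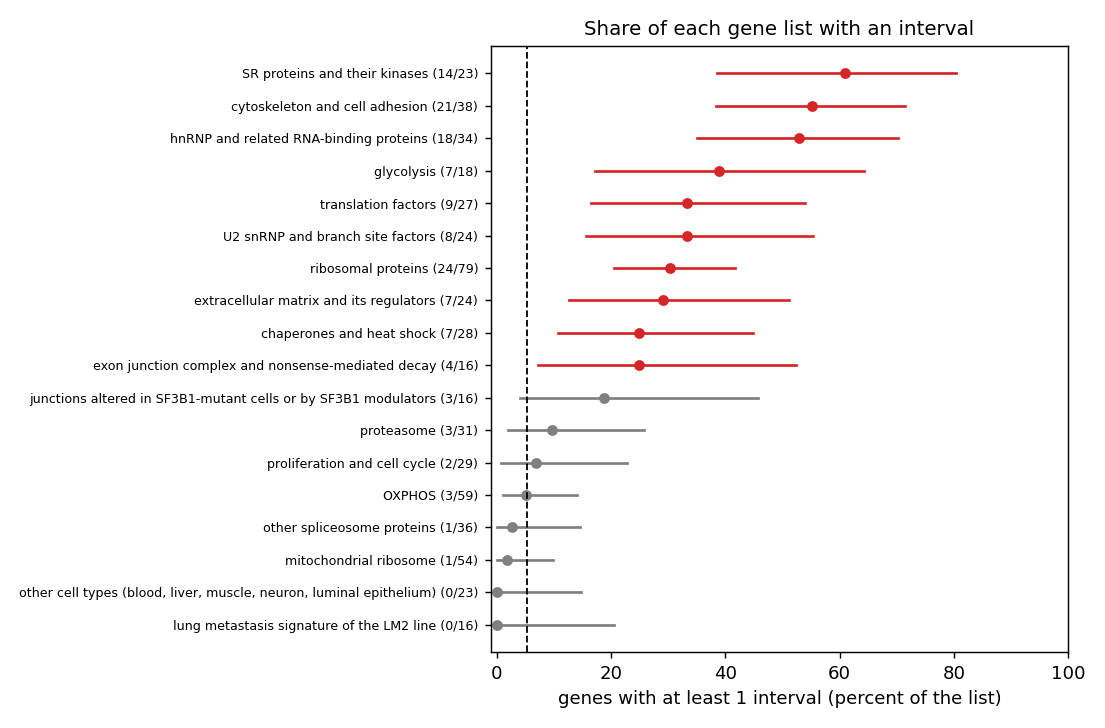
Percent of the genes of each fixed list with at least 1 interval (point) and its exact 95% interval (line); red marks an adjusted p under 0.05 and the dashed line the 5.29% of all protein-coding genes. The SR protein list is highest at 60.9%.

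Some genes held many intervals. NAV2, a gene of 776366 nt, held 9 intervals between 19726207 and 20112636 on chromosome 11, with heights up to 13 tags. HNRNPH1 held 8 intervals of 16 to 62 tags between 179616197 and 179621442 on chromosome 5, and MALAT1 held 6. LAMA5, a laminin chain, held 6 intervals of up to 23 tags and ACTB, a cytoplasmic actin, 5 of up to 14. DIP2C, DNMT1, NOP56, TEAD1 and PKM held 4 each, as did RPL10, POLE and DST, whose highest intervals were lower; 1 of those in DIP2C lay at RNA5SP298 and 1 of those in NOP56 at SNORD110. With no exon annotation used, these positions were not split into exons and introns.

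**Figure D3:**
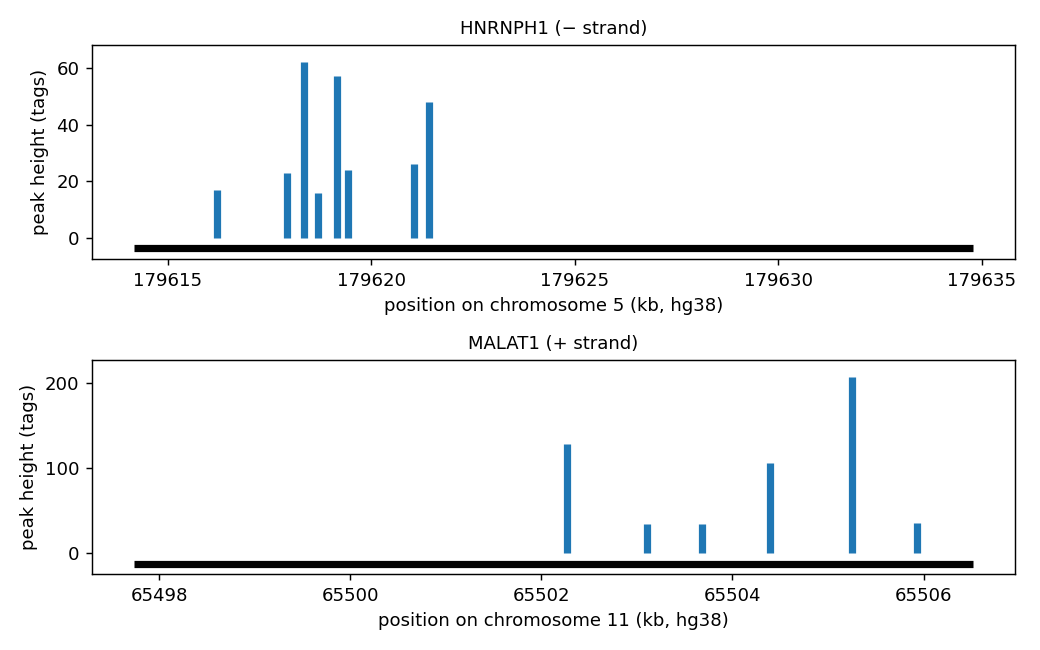
Height in tags (bars) of each interval against its position in kb (hg38) in HNRNPH1 on chromosome 5 and MALAT1 on chromosome 11; the black bar is the RefSeq gene span and bars are drawn wider than the intervals. The tallest bars are 62 tags in HNRNPH1 and 206 in MALAT1.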

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

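All tests in this part were chosen after the result was seen. In the deposited list, 38 of the 1406 distinct intervals lay in none of the genes listed for them, and the gene list comparisons do not use them. They are given for that reason alone: all exceeded the 3 tags that a count of 0 allows, but the list holds only called peaks of 3 tags or more, so their heights do not set them apart. Their greatest height was 14 tags, at RNA5S9, and 9 of them lay in no RefSeq gene. Another 9, in rRNA genes, small RNA genes or pseudogenes of small RNAs, were counted in those classes. Intervals at RNA18SP5, an rRNA pseudogene by its symbol, stayed in the class with no listed gene.

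Rows of chromosome 21 were listed under genes that do not hold them. This chromosome had 130 of the 1587 rows (8.19%) but 29 of the distinct intervals (2.06%), and U2AF1, a partner of SF3B1 at the 3′ splice site, was listed for 11 intervals. Of the 14 genes with the 113 such rows, 8 formed 4 pairs of equal span within 1%, among them U2AF1 with LOC102724594 and CBS with LOC102724560; of the intervals of the strand between the genes of a pair, 100% were listed under both, and of those beyond them, 0 were listed under either. This is consistent with spans drawn from one gene of a pair to the other, for the 74 rows of these pairs, while the 39 rows of the remaining genes were not tested. SF3B1 tags on U2AF1 stay open: 0 rows had their midpoint inside U2AF1, but tags shared with a second copy would not be unique, and no biological explanation was tested.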

How the results depend on the processing

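No paired analysis was possible because there is 1 group and 1 pooled list, which also rules out leaving out a replicate. Alternatives for splice sites, sequence, folding, 1 transcript per gene and exon-only or intron-only lists were not run, as no exon annotation or sequence was used. Added after seeing the data were the rows as listed, the listed gene numbers, the lists without small RNA intervals or pseudogenes, the 5 height classes, the snoRNA families by height, heights over expected heights, and hosts with an interval elsewhere. Of the alternatives for the main results, 53 kept direction and side of the threshold or stayed within 1.5 times. Among intervals above the median height the count was 653 and the median height 11 by construction, and the last 1 kb had a ratio of 1.14. That ratio was 1.27 with any overlap and 1.29 without genes that share an interval; the first 1 kb had 0.73 with 1 interval per gene, and other pseudogenes passed the threshold with any overlap (1.86). The protein-coding height difference was no longer past the threshold without rRNA and small RNA intervals (0), with 1 interval per gene (-0.19) and with 5 classes (-0.19). With mean log2 heights, long noncoding RNAs (0.38) and positions with no listed gene (-0.58) passed it. Lists above the background numbered 10 in each setting except intervals above the median height, with 8, where ratios of 5 called lists rose by over 1.5 times. Reversed were junctions altered in SF3B1-mutant cells among intervals above the median height (0) and oxidative phosphorylation, matched on gene span (1.40) or without pseudogenes (1.02), none past the threshold in any setting. Other than for the values set by construction, the cause was not tested. Intervals of 3 to 7 tags limit any statement on single genes.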

Other observations

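In this part, only the tests matched on gene span were set before their results were seen. Protein-coding genes with an interval were longer, with a median span of 50880 nt against 23152 nt for the others (log2 difference 1.14, permutation test, p = 0.0001, the smallest that 10000 permutations can give); among intervals above the median height the log2 difference was 0.62.

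SR protein, hnRNP and ribosomal protein genes were above the background, for which no biological explanation was tested. Gene span as the whole cause is argued against: against genes of like span (5 classes), the ratios were 14.1, 11.1 and 16.3. The median spans of these lists, 18775, 16926.5 and 5011 nt, lay below the 23152 nt of genes without an interval. Matching on span was thus likely to lower the expected numbers, and the spans themselves already go against greater length. Tags of nested small RNAs are argued against as the whole cause, since 17 hnRNP and 19 ribosomal protein genes kept an interval without them and both lists stayed past the threshold. Transcript abundance stays open and cannot be told apart from binding, because no transcript level was used; SR protein genes exceeded ribosomal protein genes (Fisher's exact test, 60.9% against 30.4%, adjusted p = 0.0132; without small RNA intervals 60.9% against 24.1%, adjusted p = 0.00188); among intervals above the median height the shares were 47.8% and 26.6%, with the call lost (adjusted p = 0.0736). This comparison was not matched on gene span, with medians of 18775 nt and 5011 nt, and the ratios matched on span have the opposite order.

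Tall intervals of protein-coding genes lay at pseudogenes of small noncoding RNAs, such as 83 tags at RNU1-11P in PHACTR1. Whether they belong to the copy and not to the host transcript at large stays open: most hosts entered the list through such an interval alone, and in hosts that also held an interval elsewhere 1 was observed, in DIP2C, a ratio of 4.54 to uniform placement (exact Poisson-binomial test, p = 0.396). Whether the tags came from the active genes and were aligned to the copies cannot be told apart from transcription of the copies, as no sequence was used; over the U1, U2, U4, U5 and U6 families, 36 active genes held 2 intervals (5.56 per 100 genes) and 1586 pseudogenes held 23 (1.45 per 100). No biological explanation was tested.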
